A study of Mus musculus with 2 samples.

How the data were processed

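The data were total RNA libraries of gastrocnemius from 2 female B6CASTF1/J mice, made from 300 ng of RNA with ERCC spike-ins added, per the labels. The spike-in label names a stranded profile for libraries with reduced ribosomal RNA, and the extraction used a Norgen tissue RNA kit, per the labels' protocols. Each library came with a gene table and 2 transcript tables. The gene table and the first transcript table hold expected counts and TPM as the authors deposited them, in the column layout that RSEM writes, with a posterior SD of each count. The first transcript table also holds each transcript's percent of its gene's TPM, per the file headers. The second transcript table holds estimated counts and TPM in the layout that kallisto writes, per the file headers. The deposited file lists name mm10 and GENCODE M21 for all of them, and state that the first tables were made from a transcriptome alignment and the second from reads. Tool names and versions are not given in the sources used here, nor is a strand setting.

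TPM has a fixed sum over all deposited rows, spike-ins included, so a rise in one abundant RNA lowers all others. The first table subtracts 99 nt from each length and the second about 338 and 344 nt. The reads came from a cross of B6 and CAST genomes and were counted on mm10, which is a B6 genome, so reads with CAST alleles can be lost. How far that moves a gene was not analysed here. Gene identifiers, names, types and coordinates were matched to GENCODE M21, in which all 55536 gene identifiers were found. The gene table held 26248 numbered rows with no gene name, with 3 reads in animal 1 and 5 in animal 2 (6.63e-06% and 1.04e-05% of counts), and a phiX row with 1 and 0 reads. These rows and the spike-ins were kept out of library sizes.

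No test between groups was possible with 1 group of 2 libraries, and no p-value across genes was computed. Values are means ± SD over the 2 animals. Fast and slow paralogues were compared as log2 of the ratio of TPM with a pseudocount of 0.1, and a ratio was called larger than the spread where its mean exceeded 2 SD with 1 sign in both animals. Expected counts were rounded to whole numbers for the scaling factors and the dispersion. Between animals, log2 ratios of expected counts were scaled with edgeR's TMM factors and a prior count of 0.5. Each list's median was set against 10000 random lists matched in 20 bins of mean expression, over genes with a mean count of 1 or more. A percentile of 0 or 100 means beyond every random list. Genes of one pathway vary together and random lists do not, so the percentile describes these libraries and is no test of a condition. Intervals of single genes are exact binomial at 95%. Intervals and limits of 3 counts cover counting error only. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

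The lists (21 gene lists and 18 lists of cell type markers), the 13 paralogue pairs, the rule for named genes and the main settings were fixed before the data were examined. Of 551 list entries, 545 matched the annotation and 6 did not. The rule named the 15 nuclear protein-coding genes of highest mean TPM, both members of each pair, and the 3 members of highest TPM per list. It also named the 8 genes furthest apart in each direction with a mean count of 100 or more (pseudogenes by count only), and the leading transcript of 18 isoform genes at 5 TPM or more. The last part named the 5 genes in each direction on which the tables differ most at 10 TPM or more. List members outside this rule were named after their values were seen, and some genes that the rule names are not reported here.

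The procedure was tested on simulated counts for the comparison of the 2 animals, drawn for 55536 genes with a dispersion of 0.04. The estimated dispersion was 0.0397. Of genes changed by a log2 of 2, 98.5% were found at 2-fold or more in the drawn direction, and 1.72% of unchanged genes with a mean count of 100 or more passed 2-fold. Of 100 unchanged lists, 2 fell outside the central 95%. Genes were drawn independently, so this rate does not cover lists whose members vary together. Alternatives were DESeq2's median of ratios, library size alone and spike-in scaling, other pseudocounts, prior counts and filters, the second transcript table, shares of expected counts, and each library left out. Ratios from the second table were centred on the gene median of the first table, not scaled with TMM. At these depths a count of 3 on a transcript of 2000 nt equals 0.0419 TPM in animal 1 and 0.0394 TPM in animal 2. Genes that share reads with near-identical copies are uncertain, which applies to Rn7s1 and Rn7s2, the haemoglobin genes, Hspa1a and Hspa1b, and mitochondrial genes with copies on chromosome 1.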

Results

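Total RNA from the gastrocnemius, the large calf muscle, of 2 female mice was sequenced after reduction of ribosomal RNA. Both mice were B6CASTF1/J animals, the first-generation offspring of a B6 and a CAST parent, at 2 months of age. The labels call the libraries biological replicates 1 and 2 of 1 group and number the mice separately, and they are called animal 1 and animal 2 here. The labels also give both the same donor record, without saying whether it stands for the strain or for 1 mouse. If the mice were not separate, every SD and difference below measures spread within 1 mouse and none between animals. Such spread could be technical or lie between the pieces of muscle taken. The libraries held about 45231400 and 47956800 expected counts. Genes at 1 TPM or more numbered 11889 in animal 1 and 11425 in animal 2. With 1 group there was no contrast of conditions. The values below describe which genes this muscle expressed and how far the animals stood apart.

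The most abundant protein-coding transcripts of the nucleus included those of the contractile apparatus and of rapid ATP supply. Skeletal alpha-actin, Acta1, led with 16485 ± 204 TPM (SD, n = 2), followed by the muscle creatine kinase Ckm at 11513 ± 31.2 TPM. Fast troponin T, Tnnt3, stood at 10332 ± 41.4 TPM, the fast regulatory light chain Mylpf at 9231 ± 518 TPM and the glycolytic enzyme Aldoa at 8394 ± 464 TPM. Atp2a1, the calcium pump of fast fibres, reached 8232 ± 730 TPM and the fast myosin heavy chain Myh4 reached 5503 ± 356 TPM. Tpm1, Tnni2, Myl1, Tnnc2, Tpm2, Pvalb, Gapdh and Mb completed the first 15, at 6470 to 2811 TPM. Together these 15 genes held 28.3 ± 0.438% of the TPM of nuclear protein-coding genes. Acta1 lies on chromosome 8, 123891769 to 123894751, minus strand, and Myh4 on chromosome 11, 67238029 to 67260446, plus strand (mm10).

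Of the 545 matched members of 39 gene lists, 419 were at 1 TPM or more in both animals. All 16 members of the fast sarcomere and calcium list were detected, and they held 6.999 ± 0.258% of all TPM (SD, n = 2). The slow list had 13 of 14 members detected and held 0.392 ± 0.191%, with 0.257% in animal 1 and 0.527% in animal 2. All 18 glycolysis and glycogen genes were detected at a median of 608 TPM, with Aldoa, Gapdh and Eno3 highest. All 30 nuclear oxidative phosphorylation genes were detected at a median of 397 TPM, and Atp5b was the highest at 1554 ± 81.9 TPM. The 13 coding genes of the mitochondrial genome held 7.25 ± 0.686% of all TPM. Reads placed on chromosome 1 copies of mitochondrial sequence are outside this share, which may therefore be too low. The copies Gm10925, Gm28437, Gm28661 and Gm29216 stood at 16765, 13926, 17775 and 8427 TPM. Markers of other cell types were lower. Fibroblast genes had a median of 29.3 TPM (14 of 14 detected), with Gsn at 386 ± 151 TPM and Dcn at 179 ± 1.53 TPM. Endothelial genes had a median of 13.7 TPM (14 of 14), and satellite cell genes 2.03 TPM (7 of 11). No neutrophil, lymphocyte or cartilage and bone gene reached 1 TPM in both animals. Pcna was the only one of 11 genes of proliferating cells that did, at 8.30 ± 0.141 TPM.

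The first gene exceeded the second in both animals in 12 of 13 fast over slow pairs. The pairs are not independent, since Myh4, Myh1 and Myh2 are all set against Myh7, which leaves 11 second genes. Of these, Actn2, paired with Actn3, is not a member of the slow list. Troponin I gave the largest mean ratio, with Tnni2 over Tnni1 at a log2 of 6.00 ± 1.81 (SD, n = 2). The calcium pumps Atp2a1 over Atp2a2 stood at 5.75 ± 1.80, troponin T (Tnnt3 over Tnnt1) at 5.75 ± 1.69, and the heavy chains Myh4 over Myh7 at 4.55 ± 1.99. In 10 of the 13 pairs the mean exceeded 2 SD. Myh1 over Myh7 (3.14 ± 1.86), Myh2 over Myh7 (2.53 ± 1.94) and Mybpc2 over Mybpc1 (0.09 ± 0.20) did not. In the second transcript table Myh1 over Myh7 did as well (mean 4.46), which made 11 pairs. The wide SDs came from a difference between the animals: the ratio was smaller in animal 2 in 12 of 13 pairs, by a median log2 of -2.46. Of the TPM of the 4 adult heavy chains, Myh4 held 62.1% in animal 1 and 56.6% in animal 2, Myh1 21.96% and 22.7%, and Myh2 14.99% and 14.3%. Myh7, the slow heavy chain, held 1.00% and 6.42%. In the second transcript table Myh4 held 53.9% and 49.3%, Myh1 33.07% and 34.9%, Myh2 12.4% and 11.9%, and Myh7 0.621% and 3.84%. No p is given, since an exact test on 2 values cannot go below a two-sided p of 0.5.

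**Figure D1:**
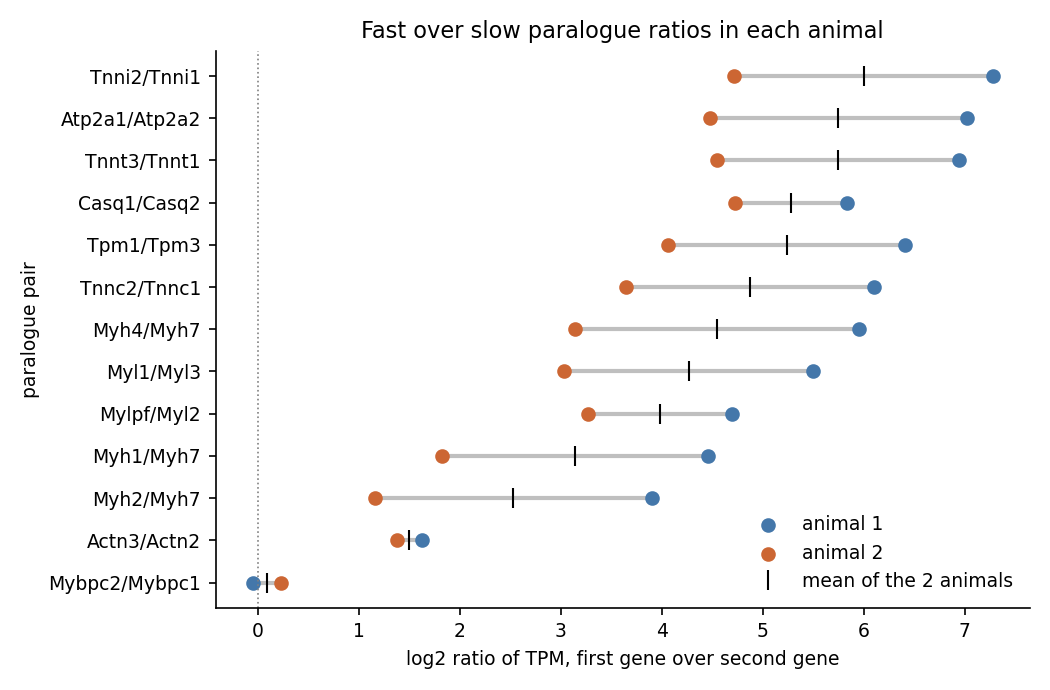
Log2 ratio of TPM of the first over the second gene (x axis) for each of the 13 paralogue pairs (y axis), in animal 1 and animal 2 (points) with their mean (black bar); the grey line joins the animals. Tnni2 over Tnni1 lies at 7.28 in animal 1 and 4.72 in animal 2, and in 12 of 13 pairs animal 2 lies to the left of animal 1.

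How far the animals differed gene by gene was measured next. Across 11697 genes at a mean of 1 TPM or more, Pearson's r of log2(TPM + 1) was 0.978 and Spearman's rho 0.969; these are correlations across genes, which are not independent replicates. The biological coefficient of variation was 0.227, from edgeR's common dispersion over 15709 genes. Of 10872 genes with a mean count of 100 or more, 329 differed by 2-fold or more, 85 higher in animal 2 and 244 higher in animal 1. With spike-in scaling the split was 137 and 174, so the share higher in animal 2 was 44.1% in place of 25.8%. Spike-in scaling moved the median log2 ratio of all genes to 0.20 and library size alone moved it to -0.11, and the ratios below are relative to the scaled main value near 0. The median log2 ratio also rose with expression. It was -0.15 at mean counts of 10 to 100, -0.03 at 100 to 1000, 0.06 at 1000 to 10000 and 0.11 above that. A small positive ratio of abundant genes is therefore partly shared by other abundant genes. The ratios are differences between 2 libraries with no replicate check, and a list is set against 10000 random lists of matched expression. Of 39 lists, 20 lay outside the central 95% of random lists, where 1.95 would fall if all genes varied independently. Genes of one pathway vary together and some lists share members, so 1.95 is no chance rate for these lists.

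Transcripts of slow fibres were higher in animal 2. The slow sarcomere and calcium list had a median log2 ratio (animal 2 over animal 1) of 1.90, or 3.74-fold, above all random lists, and 9 of its 14 members were at least 2-fold higher. Myh7 (chromosome 14, 54970684 to 54994626, minus strand) was 92.6 TPM in animal 1 and 596 TPM in animal 2, a log2 ratio of 2.75 with a 95% counting interval of 2.73 to 2.78. The slow troponins Tnni1 (36.6 and 216 TPM), Tnnt1 (83.7 and 442 TPM) and Tnnc1 (72.8 and 425 TPM), the light chain Myl3 (131 and 642 TPM) and the pump Atp2a2 (67.3 and 345 TPM) showed the same direction. Mybpc1, Csrp3 and Ankrd2 did not, with log2 ratios of -0.31, -1.33 and -0.05. The fast list stood at a median of -0.01 with no member beyond 2-fold. That was lower than all but 0.56% of random lists, and with spike-in scaling its median was 0.20 at percentile 0.46. With the main scaling, the central 95% of matched random medians ran from 0.02 to 0.19.

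Genes of oxidative metabolism were also higher in animal 2, by smaller amounts. All 30 nuclear oxidative phosphorylation genes were higher, with a median log2 ratio of 0.24 (1.18-fold, above all random lists) and a range of 0.02 for Cox7a1 to 0.37 for Sdhb. Of 19 genes of fatty acid uptake and oxidation, 17 were higher, with a median of 0.38. Fabp3, a fatty acid carrier of oxidative muscle, was 221 TPM in animal 1 and 477 TPM in animal 2, while the lipase gene Lipe was 23.7 and 6.40 TPM. The mitochondrial genome's coding genes had a median of 0.23 (12 of 13 higher, percentile 99.2), and the call ended in the second transcript table (median 0.16, percentile 90.5). It also ended over the 9 members with little read sharing, where the median stayed at 0.22 (percentile 96.8). Heat shock genes had a median of 0.39 (14 of 15 higher), with Hspa8 at 449 and 577 TPM. The 15 myogenic regulators had a median of 0.21 (10 higher, percentile 99.8). Glycolysis and glycogen genes had a median of 0.03 with no member beyond 2-fold. Its percentile was 3.64, inside the random range, and 2.07, outside it, against random lists of genes with a mean count of 50 or more.

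Fat and nerve transcripts were higher in animal 1. The adipocyte list had a median log2 ratio of -3.52, or 11.5-fold higher in animal 1, below all random lists, and 9 of 12 members differed by 2-fold or more in that direction. Cfd, the secreted factor adipsin, was 442 TPM in animal 1 and 27.6 TPM in animal 2, the adipokine gene Adipoq was 47.6 and 3.07 TPM, and the lipid droplet gene Plin1 was 38.0 and 1.30 TPM. Car3 and Plin4, which muscle also expresses, had ratios of -0.06 and -0.12, and Cidea went the other way at a low level. All 12 Schwann cell and myelin genes were at least 2-fold higher in animal 1, with a median of -2.91. The myelin genes Mbp (65.3 and 6.64 TPM) and Pmp22 (62.8 and 15.4 TPM) were among the highest of them. A liver list had a median of -2.97, and of -1.40 with a prior count of 5. Its only member at 1 TPM or more in both animals was Cyp2e1, at 20.4 and 3.14 TPM.

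**Figure D2:**
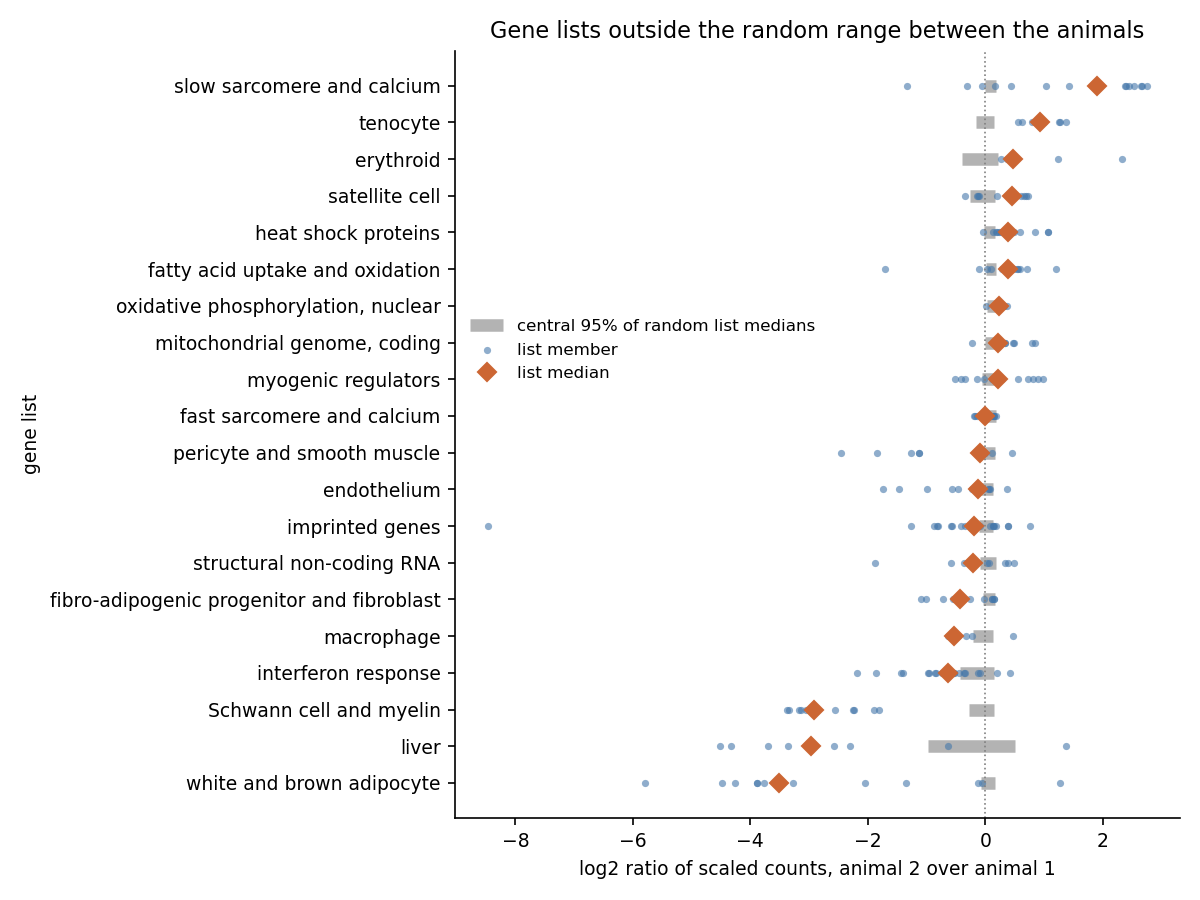
Log2 ratio of scaled counts, animal 2 over animal 1 (x axis), for the members (points) and median (diamond) of the 20 gene lists outside the central 95% of 10000 random matched lists (grey bar). The slow list has the highest median at 1.90 and the adipocyte list the lowest at -3.52; the fast, imprinted, structural non-coding RNA, endothelium and pericyte lists change sign with spike-in scaling and stay below the random range.

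Other cell types moved in different directions. All 11 tenocyte genes were higher in animal 2, with a median log2 ratio of 0.94 (1.91-fold), and Fmod, a tendon matrix proteoglycan, was 51.2 and 115 TPM. Erythroid genes had a median of 0.47 (7 of 7 higher), with the haemoglobin gene Hba-a1 at 84.8 and 111 TPM, where near-identical copies share reads. Over the 4 members with little read sharing the call ended (median 0.88, percentile 97.2). Satellite cell genes had a median of 0.45 (7 of 11 higher, none beyond 2-fold), and 0.20 over the 9 members with a mean count of 50 or more (percentile 98.9). Fibroblast genes had a median of -0.43 (10 of 14 higher in animal 1), with Col3a1 at 126 and 58.5 TPM, and Col1a1 at 168 and 173 TPM. Macrophage genes had a median of -0.52 (11 of 12 higher in animal 1), with Lyz2 at 26.8 and 16.5 TPM. Interferon response genes, of which 6 of 18 were at 1 TPM or more in both animals, had a median of -0.64 (16 of 18 higher in animal 1). The endothelial median was -0.13 and the pericyte and smooth muscle median -0.09, at percentiles 0.41 and 2.07. Spike-in scaling, which shifts all genes alike, made both positive (0.08 and 0.12) and left them below the random range (percentiles 0.51 and 1.98). The same held for the imprinted genes, with -0.19 and 0.01 (percentiles 0.23 and 0.22), and for structural non-coding RNA, with -0.20 and 0.0039 (percentiles 0.15 and 0.17). Over members with little read sharing the calls of imprinted genes and structural RNA ended (percentiles 2.53 and 32.8), and that of structural RNA also ended in the second transcript table (percentile 7.43).

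For 19 lists the median lay inside the random range. Among muscle and metabolism lists these were developmental myosin and denervation (0.05), shared filament proteins (0.11), excitation-contraction coupling (0.09), the dystrophin complex (0.10), glycolysis (0.03), creatine and adenylate kinase (0.10), the fasting response (0.12) and the circadian clock (0.08). Immediate early genes (-0.12), histones (-0.06) and ribosomal proteins (0.06) were inside it as well. In the second transcript table immediate early genes lay outside it (-0.16, percentile 1.40). Neuromuscular junction nuclei (0.02), muscle spindle (0.13), proliferating cells (0.01) and cartilage and bone (-0.01) were inside it. Over members with a mean count of 50 or more, muscle spindle (1.03, 5 members) and cartilage and bone (1.39, 2 members) lay above it. The spindle members include Myl2 (1.42), also in the slow list, and Myh6 (2.71), which shares reads with Myh7. That gain is therefore not separate from the slow-fibre difference. Neutrophil (-2.46), lymphocyte (-0.73), neuron (-0.73) and skin (-0.64) medians rested on genes of few reads. The 3 neutrophil genes lay below the range with a prior count of 5 and in the second table (percentile 1.52 in each). Their median shrank to -0.68 with that prior count and was -2.30 in the second table. Single members stood out inside these lists. Actc1, cardiac actin, was 9.71 TPM in animal 1 and 51.4 TPM in animal 2, and the metallothionein genes Mt1 (93.5 and 43.0 TPM) and Mt2 (112 and 53.1 TPM) were higher in animal 1.

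Of the genes furthest apart, the 8 highest in animal 2 were Gm34302, Myh7, Myh6, Tnni1, Tnnc1, Tnnt1, Actc1 and Gm43359, with log2 ratios of 3.35 to 2.48. Myh6 (18.0 and 125 TPM) lies next to Myh7 and shared reads with it, with a posterior SD of 39.3 reads in animal 2, and Gm34302 (37 and 377 reads) had 0 TPM in the second transcript table. The 8 highest in animal 1 were Nnat, Oxtr, Lep, Slc7a10, Lgals12, Hp, Pck1 and Plin1. Nnat, an imprinted gene on chromosome 2 (157560078 to 157562522, plus strand), had 1248 reads in animal 1 and 3 in animal 2, a log2 ratio of -8.47 with a counting interval of -10.97 to -7.14. The oxytocin receptor gene Oxtr had 1215 and 16 reads, and the leptin gene Lep (chromosome 6, 29060220 to 29073877, plus strand) had 814 and 14. Pseudogenes made up 6 of the 85 genes higher in animal 2 and 8 of the 244 higher in animal 1. Of the 329 genes, 56 belonged to one of the 39 lists.

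**Figure D3:**
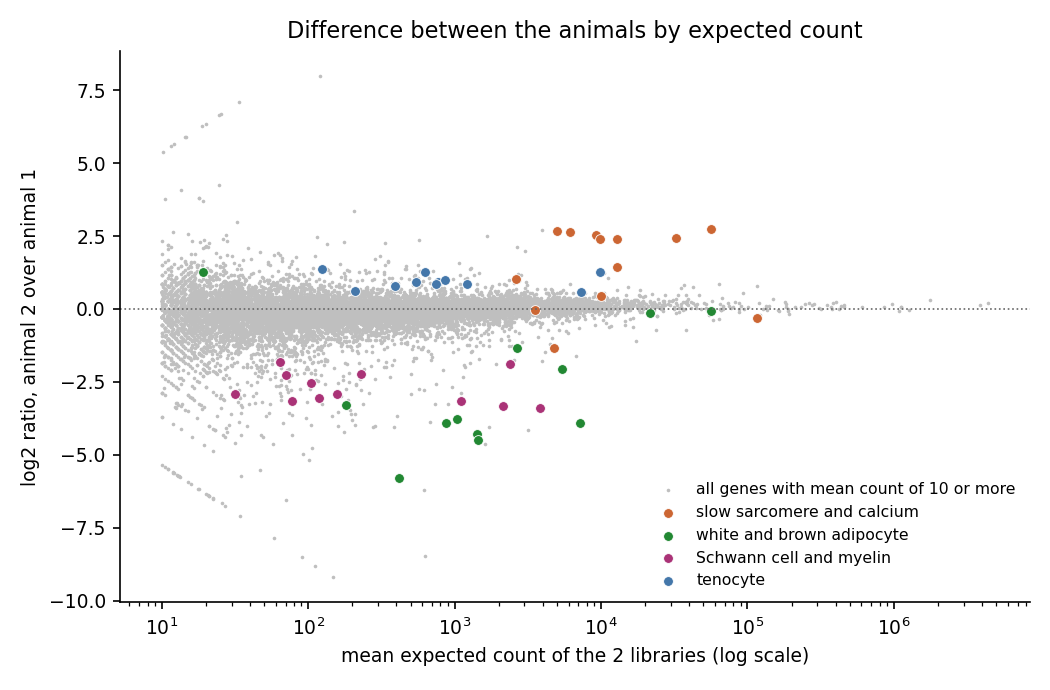
Log2 ratio of animal 2 over animal 1 (y axis) against the mean expected count of the 2 libraries (x axis, log scale) for genes with a mean count of 10 or more (grey) and the members of 4 lists (coloured). Most slow members lie above 0 with Myh7 at 2.75, tenocyte members lie above 0, and all Schwann and most adipocyte members lie below 0.

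How much of the RNA by TPM was messenger RNA depended on the table. In the gene table protein-coding genes held 45.3 ± 0.0734% of gene TPM (SD, n = 2), the misc_RNA class 30.4 ± 0.515% and mitochondrial ribosomal RNA 13.02 ± 0.886%. Rn7s1 and Rn7s2, identical copies of the signal recognition particle RNA whose reads cannot be assigned to either, held 28.7 ± 0.430% of TPM. In the second transcript table each of them was at 0.23 TPM in animal 1 and 1.09 TPM in animal 2, and protein-coding genes held 72.7 ± 1.27% of gene TPM. By expected count protein-coding genes held 76.1 ± 0.799%, since short RNAs weigh more in TPM. A run of 4 pseudogenes on chromosome 1 that copy mitochondrial sequence (Gm10925, Gm28437, Gm28661 and Gm29216) held 2.75 ± 0.0133% of gene counts. Reads of mt-Co2, at 120 ± 19.3 TPM, are therefore uncertain, and so are those of mt-Co3 and mt-Atp6. The same may hold for mt-Co1, at 17145 ± 546 TPM, since by position Gm29216 stands in its place in the run.

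Transcript tables gave the isoforms of 18 muscle genes. In 11 of the 18 a single transcript held over 50% of the gene's TPM, and in 9 of the 18 in the second transcript table. Tpm1-205 held 97.6 ± 0.233% of Tpm1 (SD, n = 2), Atp2a1-201 held 99.7 ± 0.0456% of Atp2a1 and Ryr1-202 held 94.8 ± 1.20% of Ryr1. The second table gave these 76.4%, 99.9% and 86.8%. Tnnt3-201 held 39.4 ± 0.372% of Tnnt3 over 27 annotated transcripts. The shares differed little between the animals, with a largest SD of 2.501 percentage points, for Tnnt1-203. The second transcript table named another leading transcript in 6 of the 18 genes (Tnnt3, Tnnt1, Pkm, Ttn, Myl1 and Fhl1). In Tnnt3 it put 74.3% on Tnnt3-225 and 0.0058% on Tnnt3-201.

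The 2 transcript tables of each library were then compared. Across transcripts at 1 TPM or more in either table, Pearson's r was 0.551 in animal 1 and 0.554 in animal 2, and for sums per gene it was 0.848 in each library. These are correlations across features, which are not independent. Of 5990 genes, 238 were at least 2-fold lower in the second table and 707 at least 2-fold higher by TPM as deposited. The median gene was higher in the second table by a log2 of 0.58, and with the ratios centred on that median 270 were lower and 111 higher. Rn7s1, Rn7s2, Rn7sk, mt-Atp8 and Gm23444, all of 331 nt or less, went furthest down, and Rn7sk and mt-Atp8 were listed at 0 in the second table against 14947 and 6006 TPM on average in the first. Mrpl23, Gm14506, Gm47673, Gm47283 and Gm28439 went furthest up, with Mrpl23 at 0.43 TPM and 88.2 TPM in animal 1. Among genes with 1 transcript, the second table kept a median of 0% of reads under 350 nt (34 genes), 26.2% at 350 to 500 nt (17 genes), 84.8% at 600 to 1000 nt (60 genes) and 108% over 2000 nt (528 genes).

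**Figure D4:**
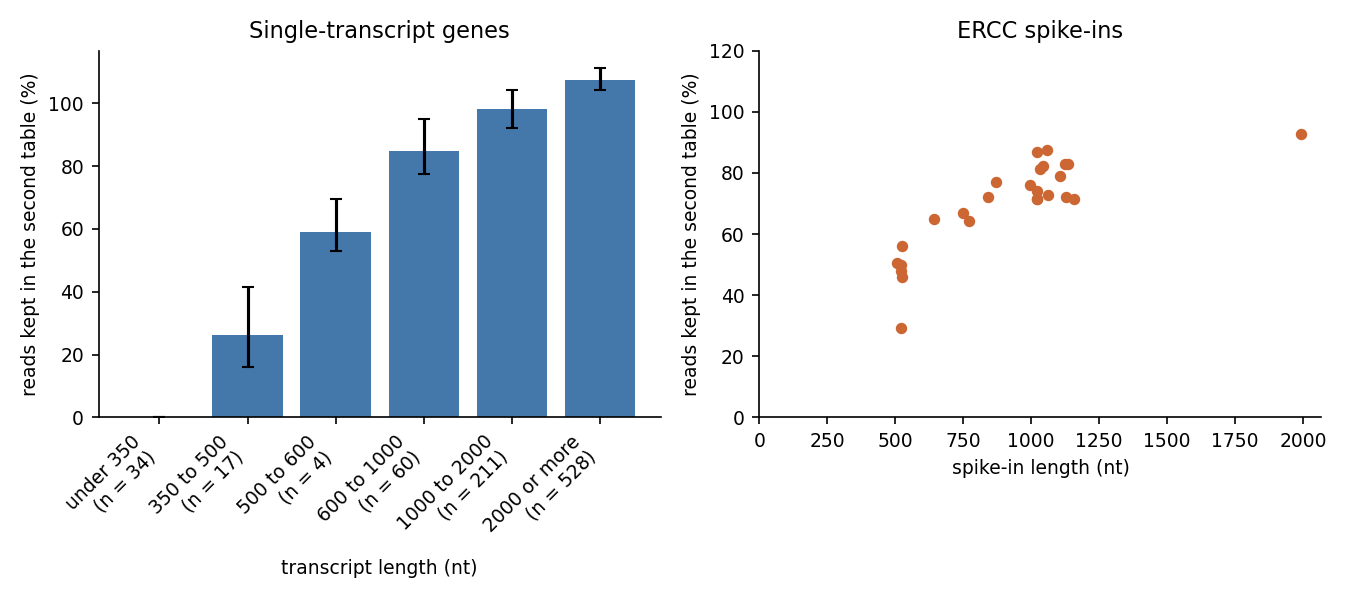
Reads in the second transcript table as a percentage of those in the first (y axes), by transcript length in nt, for genes with a single transcript (left; bars are medians, error bars the quartiles) and for 26 ERCC spike-in RNAs (right; points). Genes under 350 nt keep a median of 0% and those over 2000 nt 108%, and spike-ins under 600 nt keep 49.0%.

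Spike-in RNA of the ERCC mix, synthetic transcripts added in fixed amounts, made up 0.433 ± 0.0650% of counts (SD, n = 2), and 71 of 96 were detected in each library. The 26 spikes with a mean count of 100 or more had a median log2 ratio of -0.23 with an SD of 0.10 between spikes. Endogenous counts relative to spike-in counts were 1.24-fold higher in animal 2. The female label was compared with sex-linked genes: Xist, expressed from the inactive X, was at 18.4 and 13.8 TPM. Ddx3y, Uty, Kdm5d and Eif2s3y of the Y chromosome had 0 reads, which for a transcript of 2000 nt allows up to 0.0419 TPM in animal 1 and 0.0394 TPM in animal 2.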

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

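The tests of scaling, read sharing, fibre share and a general loss of muscle were chosen after the results were seen; the tests on second lists and on read length were written before their values were seen. One set of rows lay outside the measurements used. The 26248 numbered rows without a gene name held 3 reads in animal 1 and 5 in animal 2, too few to read as a signal. What these rows represent is not given in the sources used here.

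Slow-fibre transcripts were higher in animal 2. A difference in scaling or depth was argued against as the cause by the small span of the 4 scalings. They placed the median of all genes between -0.11 and 0.20. None could therefore have removed the slow difference, and the median log2 ratio of the 11 slow pair members stayed at 2.29 or more. Reads shared between paralogues were argued against as well, since all 11 members had a posterior SD under 1% of the count. As no member was left out, their median of 2.39 is the main median again and no separate test. The 13 fast members had a median of 0.0034, so a larger share of slow fibres, in animal 2 itself or in the piece of muscle taken from it, may account for the pattern. With 1 animal on each side these possibilities, and a change within fibres, cannot be told apart.

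Fat and nerve transcripts were higher in animal 1. A smaller share of muscle fibres that raises every other cell type alike was argued against only by medians known when the test was chosen. The tenocyte and adipocyte medians, the highest and lowest of the cell type lists, lay 4.46 log2 units apart. That gap was more than the SD of the adipocyte members (2.16), but it restates the extremes and is no separate test. The Schwann, endothelial and macrophage medians were -2.91, -0.13 and -0.52. Nerve tissue in the piece from animal 1 is a candidate explanation: a second list of 12 nerve genes, not looked at before, had a median of -2.10, past the bound of -1 set beforehand (resampled interval -2.64 to -0.74, which extends above that bound), with 3 of the 12 at 1 TPM or more in animal 2 as well. A second list of 12 fat genes had a median of -0.85, below all random lists and with 10 of the 12 at 1 TPM or more in animal 2, but it missed the bound of -1 that had been set for it, so the test did not bear out fat tissue. The miss was smaller than the range of that median over resampled members (-1.22 to -0.18), a comparison added after the value was seen. Both resampled ranges measure how unlike the listed genes are, not a spread between animals. They do not undo the miss, and whether fat tissue was in the piece stayed undecided.

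Short transcripts were lower in the second transcript table. A strand setting that discards about 1 of 2 reads was argued against, since genes with 1 transcript over 2000 nt kept a median of 108% of their reads. Genes under 350 nt kept 0.0%, those of 500 to 600 nt 59.2% (4 genes), and the length subtracted in that table was 338 and 344 nt. Values at these lengths lay in ranges set beforehand for reads dropped where an assumed fragment passes the transcript's end. Such dropping, which the sources used here do not state, cannot by itself give 108%. Genes of 600 to 1000 nt kept 84.8%, above the 72.9% that it would leave on a spike-in of 994 nt. That spike-in itself kept 76.0%. Over 26 spike-ins the share kept rose with length (Spearman's rho 0.80 across spike-ins). Single ones lay on both sides of the predicted share, such as ERCC-00046 (29.4% against 44.9%) and ERCC-00130 (87.4% against 74.8%). Such dropping remains a candidate for the shorter transcripts. No biological explanation was tested, as both tables come from the same libraries.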

How the results depend on the processing

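The tests on members with little read sharing, on shares of coding TPM, without the slow, adipocyte and Schwann lists, and on fat and nerve members under 5 TPM in animal 2 were chosen after seeing the data, as were the shares of gene types in the second table and the centred ratios between tables. The test on fat and nerve members is void, since picking members that are low in animal 2 fixes its sign. Over all alternatives, 38 values of single pairs from both animals kept their call and 1 passed it anew (Myh1 over Myh7 in the second table, for 11 pairs); for list medians 257 kept theirs (2 of them the void ones), 5 lost it, 6 gained it and 6 reversed. Calls were lost by mitochondrial, structural RNA, imprinted and erythroid genes, and gained by neutrophil, glycolysis, muscle spindle, cartilage and immediate early genes. The number of lists outside the random range was 16 to 23. Spike-in scaling reversed the fast (0.20), imprinted (0.011), structural non-coding RNA (0.0039), endothelium (0.081) and pericyte (0.12) medians in sign only, through its shift of all genes; all 5 stayed below the random range (percentiles 0.17 to 1.98). With members of little read sharing the structural RNA median was 0.038, inside the range. The fast share of TPM was 8.84% without mitochondrial genes and spike-ins, 11.1% in the second table, 10.7% of expected counts and 18.6% of coding TPM. The slow share was 0.680%, 0.599% and 1.04% in the last 3 of these settings, and the mitochondrial share 11.1% in the second table and 5.63% of expected counts. Agreement of the animals was r = 0.961 with pseudocount 0.1, 0.992 with no filter and 0.972 at 10 TPM. The coefficient of variation was 0.193 at counts of 100 or more. At mean counts of 20 and 1000, 824 and 78 genes differed by 2-fold, as more and fewer genes entered. Agreement of the transcript tables was 0.329 with pseudocount 0.1, 0.189 at 10 TPM and 0.783 with no filter. With centred ratios 381 genes in place of 945 were 2-fold apart between the tables. Protein-coding genes held 72.7% of gene TPM in the second table. Spike-ins held 0.680% of TPM. The cause of the other moves was not tested. Leaving out each animal gave a median pair ratio of 3.27 and 5.83; with 2 animals this only restates their values, and gives no call of a pair, pair count or difference between animals. Mybpc2 over Mybpc1 changed sign (-0.049 without animal 2). No paired analysis was possible because there was 1 group. Ratios spread more widely for genes of few reads: at mean counts of 10 to 100 their SD was 1.02, where counting error alone would give 0.382.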

Other observations

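The genes in these paragraphs were picked after their values were seen, and no test was run on them. Ppargc1a, a coactivator of mitochondrial genes, was 14.2 TPM in animal 1 and 24.98 TPM in animal 2, and Prox1, which is needed for slow fibre gene expression, was 0.88 and 1.65 TPM. The factor Tbx15, tied to fast glycolytic fibres, was lower in animal 2 (53.9 and 37.6 TPM). Among other transcription factor genes, Hoxd8 was 6.16 and 17.6 TPM, Hoxd9 2.53 and 5.66 TPM, Barx2 2.66 and 12.7 TPM, and Dach2 0.39 and 1.78 TPM.

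In the pericyte and smooth muscle list, 5 of 12 members were at least 2-fold higher in animal 1, and these 5 encode contractile proteins of smooth muscle. Acta2 was 58.0 and 22.1 TPM, Tagln 53.0 and 13.8 TPM, Cnn1 6.84 and 1.27 TPM, Myh11 16.9 and 7.19 TPM and Myl9 37.1 and 14.8 TPM. The pericyte genes Rgs5 (68.5 and 63.6 TPM), Abcc9 (44.1 and 44.2 TPM) and Pdgfrb (6.31 and 5.82 TPM) were close in the animals. Among endothelial genes, Vwf (22.3 and 5.48 TPM) and Fabp4 (192 and 64.5 TPM), the latter also made by fat cells, were higher in animal 1, while Cdh5 was 17.3 and 16.8 TPM.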
